A study of Populus x canadensis with 4 samples.

How the data were processed

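RNA sequencing measured transcript levels in leaves of the poplar hybrid Populus × euramericana "Neva" treated with 0, 2, 4 or 8 mM pHBA, with 1 library for each of the 4 doses. Per the labels, RNA was extracted with Trizol, treated with DNase I, required to have an RNA integrity number above 7 and sequenced on an Illumina instrument. The labels write the dose unit as mML-1, which is read here as mM. The series also names small RNA and degradome sequencing, which are not analysed here.

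The deposited table gives FPKM values made by the authors for 27630 genes of a de novo Trinity assembly, rounded to 2 decimals, and the aligner, the counting rule and their versions are not given in the sources used here. How fragments shared between related transcripts were counted is therefore unknown, which limits the values of single members of gene families. Deposited beside it are 63356 coding sequences predicted by TransDecoder and the matching gene models, used for coding length, transcript number and protein motifs. Annotation was used as deposited: 27627 genes had a match among non-redundant proteins, none weaker than a log10 E-value of −47.7, and 10543 had a SwissProt match. No genome was used. Total FPKM of the deposited values was 1174240, 1209010, 1084720 and 1070290 at 0, 2, 4 and 8 mM, so the values were not on a scale with equal totals.

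Because FPKM of a gene with 1 transcript steps by a fixed amount per fragment, the depth of each library was estimated from such genes as the depth at which low values fall nearest to whole fragments. Of 16387 such genes, the low values of 1641, 1180, 4626 and 3225 were used at 0, 2, 4 and 8 mM. At the estimated depths, 99.8%, 99.9%, 98.0% and 99.9% of the values used lay within 0.1 of a whole fragment at 0, 2, 4 and 8 mM. These depths gave fragment numbers per gene, 95% counting intervals of ratios (exact binomial), and a floor of 3 fragments. For genes with more than 1 transcript the shortest was used, with a minimum effective length. Their fragment numbers therefore tend to be too low and their counting error too large. Each gene was assigned to an organism by the species of its best protein match.

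Differences between a dose and 0 mM were taken on log2(FPKM + 1), a scale computed here from the deposited FPKM. Genes with an FPKM of at least 1 in either library were compared, and a difference of at least 2-fold on that scale was counted. No dose was tested against 0 mM, since each is 1 library, and a trend over the 4 doses was not tested. Counting error alone was simulated 20 times for each comparison from the estimated depths. In all, 41 gene lists defined by words in the annotation were compared, 34 of them also by protein motif. Each list's median was set beside 10000 random lists of the same size drawn from the same 10 expression groups, with central 95% limits at the 2.5 and 97.5 percentiles. Terms of the Gene Ontology with 15 to 300 plant genes were set beside 2000 random lists each. Gene lists, size rule, filter, pseudocount and the alternatives for them were chosen before the data were examined. The restriction to plant genes, the Gene Ontology terms and the clock genes were chosen after the data had been seen.

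Named genes followed a fixed rule, to which any gene singled out by hand after the values were seen was added. For each dose, the rule took the 5 highest and 5 lowest differences among annotated genes with an FPKM of at least 5 in either library and at least 2-fold in the same direction at all 3 doses. It also took up to 4 members of each list with the largest difference at 8 mM and an FPKM of at least 5 at 0 or 8 mM, and the member with the highest mean FPKM for phenylalanine ammonia-lyase, cinnamate 4-monooxygenase, 4-coumarate-CoA ligase, chalcone synthase, catalase and the Rubisco small chain. The rule was then applied again to plant genes alone, a step added after the data were seen. With these additions, the named genes included 182 plant genes.

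Alternatives were pseudocounts of 0.1 and 5, no filter, an FPKM of at least 5, a 4-fold size rule, genes with an open reading frame, and list members found by motif. Scaling alternatives were the upper quartile (0.75), a mean of log ratios trimmed by 30% on each side and by 5% on each side of the mean level, and the same total FPKM. These were computed over all genes, mite genes included. Scaling factors ran from 0.71 to 1.10, so none could turn the sign of a 2-fold difference. The scalings moved the all-gene median by −0.04 to +0.12 at 2 mM, −0.45 to +0.11 at 4 mM and −0.21 to +0.12 at 8 mM. A list median well beyond these shifts could not turn, so its unchanged sign is no support for it. The same plant total and length-matched random lists (5 expression by 5 length groups) were added after the data were seen.

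The steps were tested on simulated data with known differences. The changed genes were drawn only from those with a mean FPKM of at least 5, so recovery of weaker genes was not measured. With 200 such genes changed 2.5-fold, 88.5%, 91.5% and 88.0% of them were found at 2, 4 and 8 mM, and with 4-fold changes 100%, 97.5% and 98.0%, while 3.09% to 3.69% of unchanged genes passed the size rule. Counting intervals held the true ratio for 95.7%, 95.6% and 96.7% of genes. The simulated counts came from the same counting model that the intervals assume, so this checks the computation only. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and Biopython 1.88.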

Results

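Leaves of the hybrid poplar Populus × euramericana "Neva" were profiled by RNA sequencing after plants grown 90 days in water culture had spent 3 days in para-hydroxybenzoic acid (pHBA) at 0, 2, 4 or 8 mM. pHBA is a plant phenolic acid that is studied as an allelochemical, a compound by which plants affect the growth of their neighbours or of later plantings. The design asks how leaf transcript levels differ with the dose of pHBA, and the 0 mM plants are the control. Each dose was represented by 1 library made from RNA pooled in equal amounts from several plants, so none of the differences below has a replicate check and no p-value is given. Expression was given as FPKM, fragments scaled to transcript length and library size, for 27630 genes of a de novo transcript assembly. The steps between low FPKM values placed the depth at 14870000 fragments at 0 mM, 16290000 at 2 mM, 16060000 at 4 mM and 12170000 at 8 mM. At that depth 3 fragments on a transcript 1 kb long correspond to an FPKM of 0.285, 0.258, 0.261 and 0.344 at 0, 2, 4 and 8 mM. Intervals and floors given here cover counting error only. Where 4 levels of a gene are listed, they are FPKM at 0, 2, 4 and 8 mM in that order. An FPKM of at least 1 was reached by 26131 genes at 0 mM, 26415 at 2 mM, 20263 at 4 mM and 23614 at 8 mM.

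The assembly held the transcripts of more than the poplar. By the species of the best protein match, 19575 genes (70.8%) were plant genes and 7706 genes (27.9%) were genes of spider mites, nearly all of them best matched to Tetranychus urticae, a mite that feeds on leaf cells. Mite genes took 4.85% of the summed FPKM at 0 mM and 8.75% at 2 mM, but 0.493% at 4 mM and 1.98% at 8 mM. Against the control library the summed FPKM of mite genes was 1.86 times as high at 2 mM, and 0.0939 and 0.372 times the control level at 4 and 8 mM. A further 179 genes were best matched to pig, with a summed FPKM of 1566, 1198 and 1525 at 0, 2 and 4 mM and 3.45 at 8 mM. Plant genes kept 94.6%, 90.7%, 99.2% and 97.9% of the summed FPKM at 0, 2, 4 and 8 mM. Because of this mixture, gene groups below are described through their plant members. That restriction was chosen after the data were seen, and values over all members are given for some lists.

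**Figure D1:**
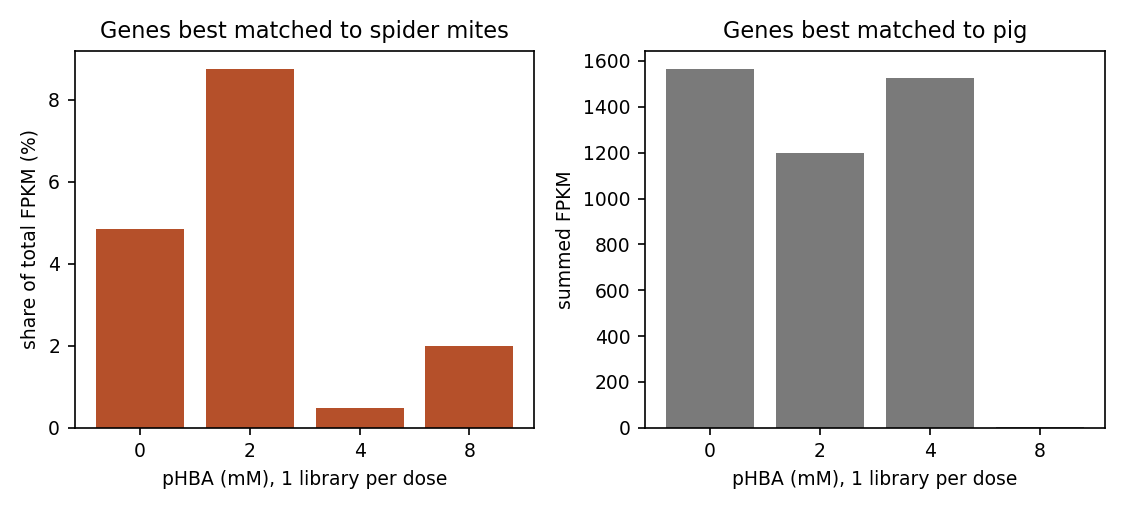
Left, the share of summed FPKM (%) held by genes best matched to spider mites at each pHBA dose (mM, 1 library per dose), which was 4.85% at 0 mM, 8.75% at 2 mM, 0.493% at 4 mM and 1.98% at 8 mM. Right, the summed FPKM of genes best matched to pig, which was 1566 at 0 mM and 3.45 at 8 mM.

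The comparison of 2 mM with 0 mM asks what the lowest dose does to the leaf transcriptome. Against a plant median log2 difference of −0.17, the xylem and secondary wall list stood higher in the 2 mM library, while the glutathione S-transferase, phenylpropanoid, cytochrome P450 and WRKY lists stood lower. Mite genes took 8.75% of FPKM, against 4.85% in the control. The xylem and secondary wall list had a median log2 difference of +0.61, with 11 of its 32 plant members at least 2-fold higher and 2 at least 2-fold lower. Among its members, laccase-4 (TRINITY_DN13990_c0_g3), an oxidase of lignin precursors, was at 10.1, 24.6, 2.61 and 0.15, and fasciclin-like arabinogalactan protein 11 (TRINITY_DN11253_c0_g5), a secondary-wall protein, was at 15.9, 35.3, 2.64 and 0.25, both on 2 fragments at 8 mM. Glutathione S-transferases, which conjugate foreign compounds, had a median of −0.42 over 37 plant members (7 at least 2-fold lower, 1 higher). Over all 60 members, 17 of them mite genes, that list's median was −0.06. The phenylpropanoid and lignin list had a median of −0.31 (5 of 43 lower), cytochrome P450s −0.30 (30 of 152 lower, 5 higher) and WRKY transcription factors −0.32 (8 of 62 lower, 1 higher). The medians of all 5 of these lists kept their sign under every scaling between libraries that was tried, although none of the scalings could turn medians of this size. Other lists of detoxification and phenolic metabolism lay within the central 95% of random lists: flavonoid and tannin genes at −0.24, UDP-glycosyltransferases at −0.18 and MATE efflux carriers at −0.11, the last of which turned under upper-quartile scaling.

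Aquaporins, which are water channels, had a median of +0.22 over 29 plant members, and expansins with xyloglucan endotransglucosylases, which loosen cell walls, had +0.26 over 35 but −0.18 when members were found by protein motif. Kunitz inhibitors with polyphenol oxidases had −0.60 over 14 members (6 lower, 1 higher), with an interval over genes of −3.05 to +0.53. ABC transporters had −0.31 and the NBS-LRR immune receptors −0.28. None of these 5 medians changed sign under another scaling, but the scalings used at 2 mM were too small to turn them. Single genes with large differences included amino acid permease 3 (TRINITY_DN16352_c0_g4), an importer of amino acids, at 7.73, 58.9, 23.5 and 16.6. A FLOWERING LOCUS C-like MADS-box gene (TRINITY_DN14724_c0_g3) was at 61.6, 2.39, 10.8 and 14.2, an MtN26 family gene (TRINITY_DN12826_c1_g5) at 278, 17.2, 37.3 and 59.3, and WRKY75 (TRINITY_DN16032_c1_g8) at 50.1, 10.6, 4.33 and 8.06. A polyphenol oxidase (TRINITY_DN10971_c1_g2), an enzyme that turns phenolics into quinones in damaged leaves, was at 100.04 in the control and 5.59, 5.74 and 20.2 at 2, 4 and 8 mM. By contrast the Kunitz-type trypsin inhibitor D2 (TRINITY_DN13140_c0_g7), a poplar inhibitor of digestive proteases, was at 182 in the control and 599 at 2 mM, and at 0.27 and 0 at 4 and 8 mM. Transcripts named XYLEM CYSTEINE PEPTIDASE 2 and KAN4 (TRINITY_DN11816_c1_g5 and TRINITY_DN12881_c0_g10) were listed at 0 in the control and at 8.72 and 5.87 at 2 mM, each on fewer than 8 fragments. They were at 1.24 and 7.58 at 4 mM and at 1.60 and 3.27 at 8 mM. A geranylgeranyl pyrophosphate synthase transcript (TRINITY_DN10908_c1_g4) was at 9.34 in the control on 16 fragments and was listed at 0 at the other doses.

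Across the whole table, 2641 genes were at least 2-fold higher and 1102 at least 2-fold lower at 2 mM on the log2(FPKM + 1) scale, among 27151 genes with an FPKM of at least 1 in either library. Mite genes made up 74.8% of the higher genes. Among 19118 plant genes, 640 were higher and 976 lower, and counting error alone gave a mean of 209.5 higher and 200.1 lower plant genes in 20 simulations. The 95% counting interval of the ratio excluded no difference for 392 of the higher and 738 of the lower plant genes. Plant members of 14 of the 41 lists had a median above, and of 8 lists a median below, the central 95% of 10000 random plant gene lists matched on expression. These percentiles describe the 2 libraries and are not tests of the treatment.

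The comparison of 4 mM with 0 mM showed lower medians of the jasmonate lists in the 4 mM library, together with lower medians of the phenylpropanoid and secondary-wall lists. The genes that make jasmonate, the hormone of wounded leaves, had a median log2 difference of −1.10, with 17 of 32 plant members at least 2-fold lower and 3 higher. The JAZ repressors, whose own transcripts follow jasmonate, had a median of −1.85 (8 of 14 lower, 0 higher), and Kunitz inhibitors with polyphenol oxidases −2.00 (9 of 14 lower, 0 higher). Each of the 3 medians was below all 10000 random lists and kept its sign under every scaling, although no scaling used could turn a median of this size. The Kunitz and polyphenol oxidase median was −0.86 over all 20 members and −0.13 over the plant members found by protein motif. The Gene Ontology term response to wounding, 36 plant genes, went the other way at +0.53, or +0.04 under upper-quartile scaling. The mite share of FPKM was 0.493% in this library against 4.85% in the control.

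Allene oxide cyclase (TRINITY_DN11559_c0_g5), which closes the ring of the jasmonate precursor, was at 1620.1, 1352, 204 and 273. Linoleate 13S-lipoxygenase 3-1 (TRINITY_DN17196_c0_g3), an earlier step of the same pathway, was at 434, 247, 53.3 and 75.2, and JAZ5 (TRINITY_DN11816_c1_g1) at 494, 400.2, 34.8 and 101. Endochitinase WIN8 (TRINITY_DN13881_c1_g2), a wound-induced chitinase of poplar, was at 1301, 2086, 9.83 and 28.9, a log2 difference of −6.91 at 4 mM. The related WIN6 (TRINITY_DN10809_c7_g1) was at 4344, 7433, 133 and 179. Kunitz inhibitor D2, on 2 fragments at 4 mM, had a ratio to the control of 0.00148 with a counting interval of 0.000177 to 0.00529. Pathogenesis-related proteins as a list had a median of −0.45, with 30 of 86 plant members lower and 2 higher, and −0.64 over all 98 members.

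Lists of enzymes that make or polymerize phenolics and terpenes also had negative medians at 4 mM. The phenylpropanoid and lignin list had a median of −0.64, with 19 of 43 members lower and 0 higher. Its entry enzyme phenylalanine ammonia-lyase G4 (TRINITY_DN16175_c1_g1) was at 744, 478.4, 141 and 124, cinnamate 4-monooxygenase (TRINITY_DN14610_c0_g2) at 609, 425, 125 and 119, and 4-coumarate-CoA ligase 1 (TRINITY_DN15899_c2_g1) at 339, 225, 52.7 and 69.0. Isoeugenol synthase 1 (TRINITY_DN13759_c0_g5), an enzyme of phenylpropene volatiles, had the lowest differences at 4 and 8 mM among the named genes lower at all 3 doses, at 180.5, 33.4, 0.81 and 2.73 (log2 −6.65 at 4 mM). Berberine bridge enzyme-like 28 (TRINITY_DN14166_c1_g1), an oxidase, was at 438, 149.7, 3.43 and 12.95, a cannabidiolic acid synthase-like 1 gene (TRINITY_DN10969_c2_g4) of the same family at 91.7, 8.15, 2.64 and 14.9, and the lignin oxidase laccase-12 (TRINITY_DN16111_c0_g1) at 535, 185, 12.8 and 56.7. Class III peroxidases, which oxidize phenolics in the wall, had a median of −1.07 (19 of 37 lower, 3 higher). Terpene synthases had −2.13 over 8 members (6 lower, 1 higher), with a 95% interval of the median over genes of −5.44 to +1.66. The xylem and secondary wall list stood at −1.24, with 18 of 31 members lower and 1 higher. None of these 4 list medians changed sign under another scaling, although no scaling used could turn negative medians of this size. With a pseudocount of 5 the 4 mM medians shrank to −0.59 for class III peroxidases, −1.32 for terpene synthases, −0.76 for the xylem list, −0.64 for jasmonate synthesis and −0.26 for pathogenesis-related proteins.

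Some lists and genes stood higher at 4 mM, where the plant median was +0.22 and went to −0.25 under upper-quartile scaling. The Calvin cycle list had a median of +0.65 over 14 genes, positive under every scaling but at +0.16 under the upper-quartile one. Its interval over genes was −0.49 to +0.79, with 1 member at least 2-fold higher and 1 lower. Rubisco activase (TRINITY_DN14957_c1_g3), which keeps Rubisco active, was at 8798, 10061, 15221 and 16325. The small chain of Rubisco itself (TRINITY_DN10927_c0_g1) was at 3469, 3477, 4230.2 and 3792, with differences at 4 and 8 mM whose sign turned under upper-quartile scaling. The abscisic acid and PP2C list had a median of +0.33 (11 of 91 higher, 3 lower), which became −0.12 under upper-quartile scaling. Protein phosphatase 2C 37 (TRINITY_DN14728_c0_g2), of the family that restrains abscisic acid signalling, was at 69.7, 76.3, 256 and 348. ABC transporters had a median of +0.45, with 29 of 120 plant members higher and 7 lower, and +0.07 over all 164 members, 43 of them mite genes. The plant median of ABC transporters went to 0.00 under upper-quartile scaling. NBS-LRR receptors had +0.43 (22 of 109 higher, 8 lower), a sign that turned under upper-quartile scaling. Light-harvesting proteins, at +0.12, changed sign under upper-quartile and trimmed-mean scaling.

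In total 2134 genes were at least 2-fold higher and 8424 at least 2-fold lower at 4 mM among 27027 compared. Mite genes made up 79.0% of the lower genes. Of 19452 plant genes, 2091 were higher and 1715 lower, where counting error alone gave means of 220 and 203.4. Counting intervals excluded no difference for 1720 of the higher and 1568 of the lower plant genes. Plant members of 5 lists had a median above and of 20 lists a median below the central 95% of random lists. Upper-quartile scaling turned the plant split to 937 higher and 2802 lower, so the balance of directions at this dose depends on the scaling. That quartile was taken over all genes, and mite genes with an FPKM of at least 1 numbered 7192 at 0 mM and 1045 at 4 mM. Its factor of 0.71 therefore also reflects which mite genes passed. The same plant total gave a factor of 1.03, with 2269 plant genes higher and 1658 lower. Plant differences were also larger in genes with longer coding sequences, with a median of +0.10 in the shortest of 10 length groups and +0.50 in the longest at 4 mM, and +0.02 and +0.47 at 8 mM.

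**Figure D2:**
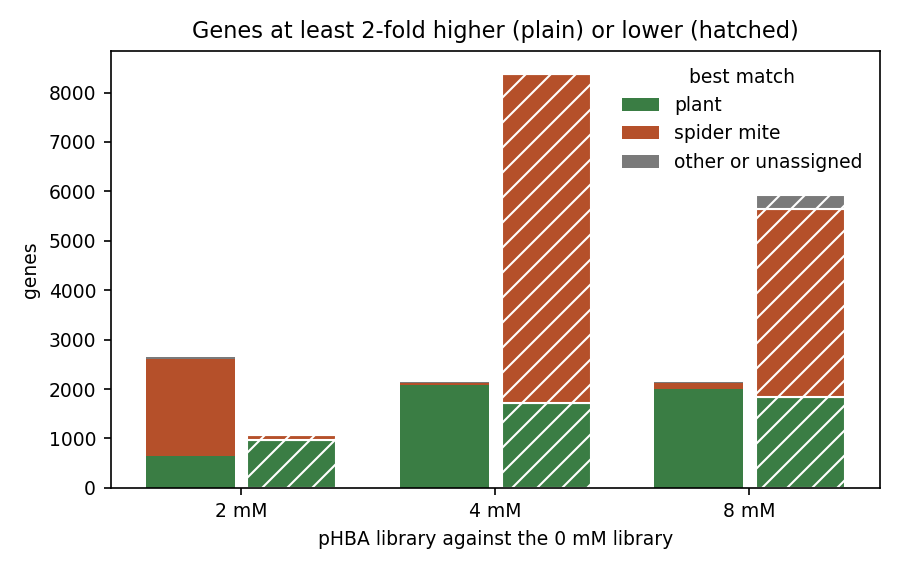
Number of genes at least 2-fold higher (plain bars) or lower (hatched bars) than at 0 mM in the 2, 4 and 8 mM libraries, stacked by the organism of the best protein match. Of 8424 lower genes at 4 mM 6656 were spider mite genes, against 1715 plant genes.

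The comparison of 8 mM with 0 mM, the highest dose, gave a picture close to that of 4 mM, with lower medians of the jasmonate and secondary-wall lists. Flavonoid and tannin genes had a median of −0.56 at 8 mM, against −0.45 at 4 mM and −0.24 at 2 mM, and 13 of 32 were at least 2-fold lower at 8 mM with 2 higher. The intervals over genes were −1.92 to +0.23 at 8 mM and −1.35 to +0.44 at 4 mM. For the 27 members with a mean FPKM of at least 5 the 4 mM median was −0.022, within the central 95% of random lists. Chalcone synthase 1 (TRINITY_DN15500_c0_g2), the first enzyme of flavonoid synthesis, was at 166, 62.6, 18.3 and 9.19, and dihydroflavonol 4-reductase (TRINITY_DN13001_c0_g1), a step toward tannins and anthocyanins, at 91.2, 80.1, 15.9 and 6.51. Jasmonate synthesis had a median of −1.17 (16 of 31 lower, 2 higher), JAZ repressors −1.27 (9 of 14 lower, 0 higher), and Kunitz inhibitors with polyphenol oxidases −0.77 (6 of 14 lower, 0 higher). Every one of these 4 lists lay below all 10000 random lists at 8 mM and kept its sign under every scaling, although no scaling used could turn medians of this size. The Kunitz and polyphenol oxidase median had an interval over genes of −2.79 to +0.20, and it was −1.76 over all 20 members and turned to +0.022 over plant members found by protein motif. Mite genes took 1.98% of FPKM in this library.

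Several genes of the jasmonate, JAZ and pathogenesis-related lists were less far below the control at 8 mM than at 4 mM. JAZ5 was at 34.8 at 4 mM and 101 at 8 mM, WIN8 at 9.83 and 28.9, and allene oxide cyclase at 204 and 273. A second set was lowest at 8 mM. Cytochrome P450 71A1 (TRINITY_DN14110_c1_g3), of a family that oxidizes metabolites, was at 659, 1360.3, 66.3 and 3.97, and GDPD2 (TRINITY_DN14105_c0_g2), which releases glycerol 3-phosphate from phosphodiesters, at 465, 146, 27.0 and 9.76. Inorganic pyrophosphatase 1 (TRINITY_DN15169_c0_g1) was at 140.03 in the control and 65.9, 13.3 and 6.42 at 2, 4 and 8 mM. A Bet v 1k family gene (TRINITY_DN14506_c2_g2), of the pathogenesis-related list, was at 68.7, 92.8, 1.67 and 0, and Kunitz inhibitor D2 was listed at 0 at 8 mM too. DMR6-like oxygenase 2 (TRINITY_DN12166_c1_g1) was at 22.5, 4.67, 1.18 and 0, with 3 fragments at 4 mM.

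Lists of secondary-wall, cell-wall and water-channel genes had negative medians at 8 mM. The xylem and secondary wall list had a median of −1.87, with 20 of 29 members lower and 1 higher, the lowest median of any list with at least 10 members at this dose. Laccase-2 (TRINITY_DN12566_c2_g1) was at 227, 101, 8.24 and 13.8, and tubulin alpha-3 (TRINITY_DN12950_c0_g2), a cytoskeletal subunit, at 32.5, 76.0, 4.39 and 1.25. Fasciclin-like protein 11 was at 0.25 at 8 mM on 2 fragments, a ratio to the control of 0.0157 with a counting interval of 0.00187 to 0.0572. Expansins with xyloglucan endotransglucosylases had a median of −0.81 (14 of 34 lower, 5 higher), aquaporins −0.48 (6 of 29 lower, 1 higher), class III peroxidases −0.90 and glutathione S-transferases −0.49 (−1.10 by protein motif). All were negative under every scaling, but no scaling used could turn medians of this size. By protein motif the expansin and xyloglucan list was at −0.18 at 8 mM. With a pseudocount of 5 the 8 mM medians shrank to −0.98 for the xylem list, −0.58 for class III peroxidases, −0.49 for expansins with xyloglucan genes and −0.63 for jasmonate synthesis. Members went opposite ways within the aquaporins: PIP2-2 (TRINITY_DN10841_c0_g1) was at 270.3, 393, 31.5 and 57.4, and PIP2-8 (TRINITY_DN10841_c1_g2) at 106, 218, 335 and 312.

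Some lists and genes stood higher at 8 mM. The Calvin cycle list had a median of +0.66 with an interval over genes of −0.01 to +0.87 and 1 of 14 members at least 2-fold higher and 1 lower, and sedoheptulose-1,7-bisphosphatase (TRINITY_DN17040_c0_g1) was at 351, 393, 566 and 602. Catalase-1 (TRINITY_DN14451_c0_g1), which removes hydrogen peroxide, was at 1274, 1486, 1846 and 2139. ABC transporters had +0.49 (29 of 118 higher, 9 lower), or +0.26 by protein motif and +0.29 with a pseudocount of 5. NBS-LRR receptors had +0.37 (19 of 110 higher, 8 lower) and the abscisic acid and PP2C list +0.29 (13 of 91 higher, 5 lower). None of these list medians changed sign under another scaling at this dose, where the scalings used were too small to turn them. Within these lists the cuticle-lipid exporter ABCG11 (TRINITY_DN16642_c1_g1) went the other way, at 308, 162, 36.8 and 45.3, and so did a disease resistance response protein 206 (TRINITY_DN11030_c1_g2), a dirigent-type protein that the NBS-LRR list takes by name, at 489, 268, 51.5 and 40.7. The transcription factor NAC21/22 (TRINITY_DN12984_c0_g2) was at 7.86, 6.92, 51.9 and 101, and NAC29 (TRINITY_DN15302_c0_g1) at 27.8, 21.4, 136 and 155. Protein phosphatase 2C 78 (TRINITY_DN14131_c1_g3) was at 5.06, 4.15, 33.8 and 52.4, and ferredoxin-dependent glutamate synthase (TRINITY_DN9678_c0_g1), an enzyme of ammonium assimilation, at 45.6, 39.6, 149 and 189. The genes with the highest differences among those higher at all 3 doses had few fragments: an ABC transporter family transcript (TRINITY_DN10245_c0_g2) was at 0, 1.76, 21.6 and 14.2, with 9 fragments at 8 mM, and an NADH-dependent glutamate synthase transcript (TRINITY_DN18249_c0_g3) at 3.71, 9.33, 70.6 and 65.8, a ratio at 8 mM of 17.7 with a counting interval of 5.16 to 81.4.

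Further stress and regulatory lists went different ways. AP2/ERF transcription factors, many of which act in stress responses, had medians of −0.21, −0.31 and −0.21 at 2, 4 and 8 mM, with 22 of 77 at least 2-fold lower and 4 higher at 4 mM. These medians were negative under every scaling, although none of the scalings used could turn them. MYB factors had −0.04 and −0.15 at 4 and 8 mM, where the 4 mM sign turned under scaling to the same total, with 38 of 132 lower and 12 higher at 8 mM. For MYB members found by protein motif the medians were −1.11 and −1.41. NAC factors had +0.14 and +0.23, the former turning under upper-quartile and trimmed-mean scaling, and cytochrome P450s −0.07 and −0.16, the former turning under scaling to the same total. Small heat shock proteins, which are chaperones, had −0.21, +0.41 and −0.26 over 16 genes, and the 4 mM sign turned under upper-quartile scaling. HSP70 chaperones had +0.37 over 22 plant members at 4 mM, a sign that turned under the same scaling, and +0.24 over 21 at 8 mM, which turned to −0.75 for members found by protein motif. The 9 HSP90 chaperones had +0.59 and +0.36 and the 3 catalases +0.53 and +0.60, positive under every scaling at both doses, although over all 13 HSP90 genes the 8 mM median was +0.0073 and over all 5 catalases the 4 mM median was −0.12. Upper-quartile scaling took the 4 mM values to +0.12 for HSP90 and +0.03 for catalases. These HSP90 and catalase medians lay within the central 95% of random lists matched on expression and coding length. Superoxide dismutases had +0.41 and +0.04, UDP-glycosyltransferases +0.08 and +0.03, and MATE efflux carriers +0.20 and +0.13, and each of these 6 medians turned under upper-quartile scaling. Over all members, mite genes included, superoxide dismutases were at −0.11 at 8 mM, and UDP-glycosyltransferases at +0.08, −0.24 and −0.21 at 2, 4 and 8 mM. Auxin response genes had −0.06 and −0.07, which turned under scaling to the same total. A heat stress factor B-3 gene (TRINITY_DN13040_c0_g1) was at 117, 39.3, 6.30 and 13.02, and a LEA protein D-29-like gene (TRINITY_DN11409_c0_g3), of a desiccation-protein family, at 1.35, 2.58, 19.2 and 19.1.

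In total 2136 genes were at least 2-fold higher and 5920 at least 2-fold lower at 8 mM among 27140 compared, and mite genes made up 64.0% of the lower genes. Of 19404 plant genes, 2009 were higher and 1844 lower, where counting error alone gave means of 229.7 and 253.8. Counting intervals excluded no difference for 1613 of the higher and 1616 of the lower plant genes. Plant members of 4 lists had a median above and of 19 lists a median below the central 95% of random lists. Upper-quartile scaling gave 1388 higher and 2313 lower plant genes.

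**Figure D3:**
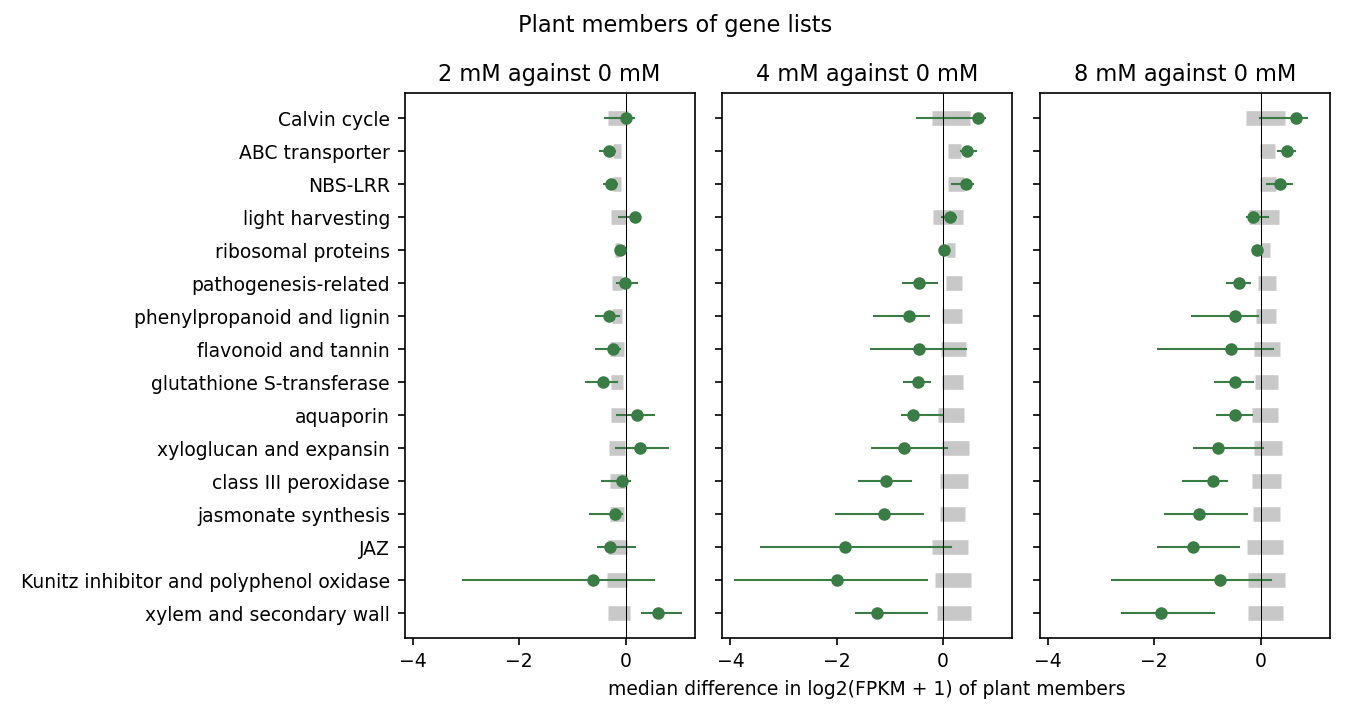
Median difference in log2(FPKM + 1) against 0 mM (x axis) of the plant members of 16 gene lists at 2, 4 and 8 mM, with points for medians, green lines for their 95% intervals over genes and grey bars for the central 95% of 10000 random lists matched on expression. The xylem and secondary wall list lay at +0.61, −1.24 and −1.87, and the NBS-LRR (at 4 mM), light harvesting (at 4 mM), ribosomal protein (at all 3 doses), Calvin cycle (at 2 mM), class III peroxidase (at 2 mM) and pathogenesis-related (at 2 mM) medians changed sign under at least 1 other scaling.

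**Figure D4:**
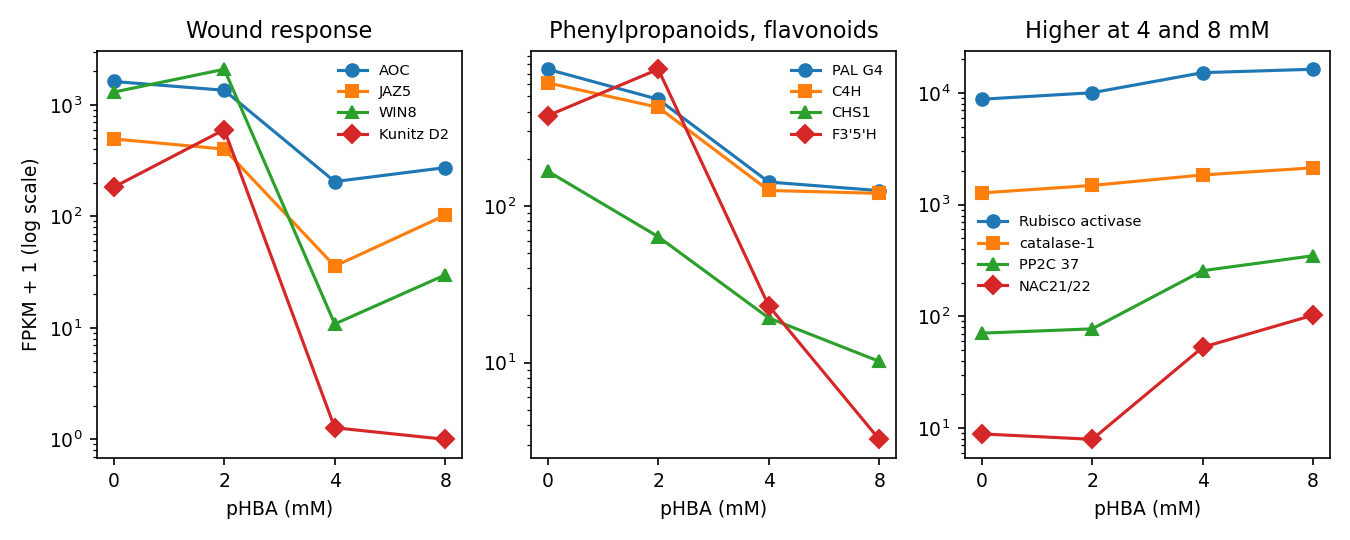
FPKM + 1 (log scale) of 12 named plant genes against pHBA dose (mM), 1 library per dose, grouped as wound-response genes, phenylpropanoid and flavonoid genes and genes that stood higher at 4 and 8 mM. WIN8 was at 1301, 2086, 9.83 and 28.9 FPKM and protein phosphatase 2C 37 at 69.7, 76.3, 255.5 and 348 FPKM over the 4 doses.

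Genes that differed in the same direction at all 3 doses address whether any response holds from 2 to 8 mM. Among 18957 plant genes compared at every dose, 279 were at least 2-fold lower and 165 at least 2-fold higher at 2, 4 and 8 mM. The lower ones included isoeugenol synthase 1, berberine bridge enzyme-like 28, GDPD2, the laccases 2 and 12, and WRKY75. The higher ones included the WAT1-related gene At4g30420 (TRINITY_DN11113_c1_g5), of a transporter family, at 4.26, 15.7, 52.0 and 35.6. Of the plant genes, 51 were lower and 48 higher in the order of dose. Since the 3 comparisons share the control library, counting error alone gave 25.6 lower and 63.2 higher plant genes in simulation, and lists independent of each other would share 8.59 and 3.94. With 1 control library it cannot be split, and part of the excess can come from that library. At 4 and 8 mM together, 1293 plant genes were lower and 1156 higher, where independent lists would share 167 and 145. A further 93 plant genes were higher at 2 mM and lower at both 4 and 8 mM, and 34 went the other way. Over all genes, mite genes included, 356 were lower and 177 higher at the 3 doses, where counting error alone gave 56.6 lower and 130.1 higher.

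The agreement between doses asks whether the same plant genes differ at each. At 4 and 8 mM the log2 differences of 19563 plant genes had a correlation of 0.86 across genes, which are not independent replicates. The 2 mM differences correlated with those at 4 mM at 0.26 and with those at 8 mM at 0.19. Unchanged libraries against the shared control gave simulated correlations of 0.50, 0.53 and 0.50 for these 3 pairs, so the values need the covariances beside them. The covariance was 0.716 for 4 with 8 mM against 0.0492 simulated, 0.137 for 2 with 4 mM against 0.0481, and 0.0967 for 2 with 8 mM against 0.0486. In contrasts that share no library, 4 against 0 mM with 8 against 2 mM correlated at 0.65, 8 against 0 mM with 4 against 2 mM at 0.73, and 2 against 0 mM with 8 against 4 mM at −0.15. Between 8 and 4 mM directly, 485 plant genes were higher and 565 lower at 8 mM. Over all 27614 genes the correlations were 0.81 for 4 with 8 mM, −0.20 for 2 with 4 mM and −0.05 for 2 with 8 mM, with the mite genes included.

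**Figure D5:**
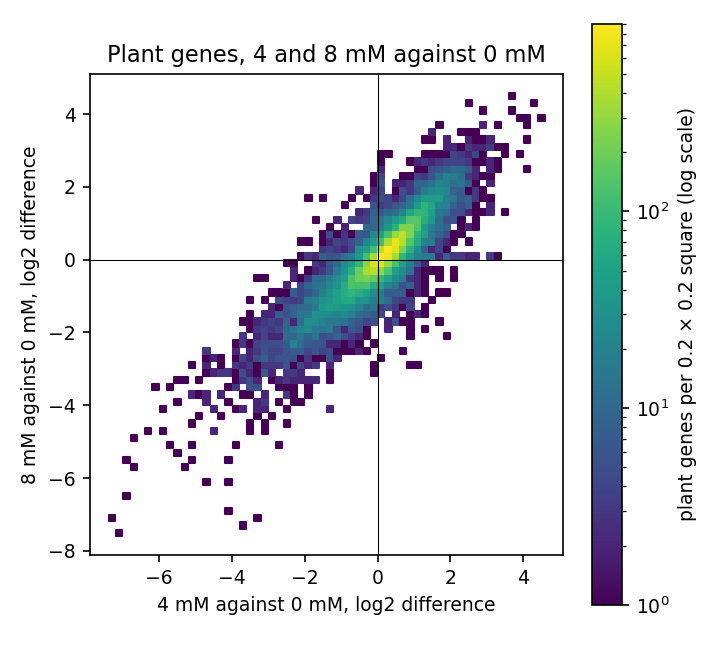
Density of 19563 plant genes by their log2 difference from 0 mM at 4 mM (x axis) and at 8 mM (y axis), coloured by the number of genes per square on a log scale. The cloud runs along the diagonal, and the correlation across genes was 0.86.

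Marker lists describe the other tissues, organisms and RNA fractions that a leaf sample can hold. The xylem and secondary wall list was fixed as such a marker list too, with medians of +0.61, −1.24 and −1.87 at 2, 4 and 8 mM. A different share of such tissue between the samples and a different expression within it cannot be told apart here. The phloem list had medians of +0.10, −0.24 and −0.20 at 2, 4 and 8 mM over 15 genes, with the same signs under every scaling, none of which could turn them. Its member sieve element occlusion B (TRINITY_DN18021_c1_g1), a sieve-tube protein, was at 31.3, 41.6, 17.4 and 16.4. The epidermis and cuticle list had +0.15, −0.01 and −0.19, of which the 4 mM sign turned under scaling to the same total. Senescence genes had −0.12, +0.14 and −0.03, and the signs at 4 and 8 mM turned under at least 1 other scaling, and over all 59 members the 4 mM median was −0.05. STAY-GREEN (TRINITY_DN18084_c1_g2), which acts in chlorophyll breakdown, was at 6.24, 12.2, 1.66 and 1.09. The 235 plant ribosomal protein genes had medians of −0.10, +0.02 and −0.08, with a sign that turned at every dose under some scaling, and at most 5 of them differed 2-fold at any dose. Over all ribosomal proteins, 129 of them mite genes at 4 mM, the medians at 4 and 8 mM were −0.13 and −0.32. The list meant for plastid- and mitochondrion-encoded genes took nuclear genes by its name pattern, with plant medians of −0.11, +0.01 and −0.06 whose signs all turn under some scaling, and is no measure of organelle RNA. The non-plant list, built on words in gene names, held only 7 of the 7706 mite genes, so mite RNA was measured by the species of the best match.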

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

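These values were selected after the result was seen, and no replicate stands behind them. Spider mite genes stood out because their summed FPKM went one way at the lowest dose and the other way at the higher doses, at 1.86 times the control level at 2 mM, 0.0939 times at 4 mM and 0.372 times at 8 mM; the difference was not tested. The plant members of the xylem and secondary wall list stood out in the same way, with medians of +0.61 at 2 mM, −1.24 at 4 mM and −1.87 at 8 mM. No scaling alternative turned these signs, and none could at this size. The difference was not tested. The 3 assembled genes best matched to enterovirus, outside the plant measurement, had a summed FPKM of 23.56 at 8 mM and were listed at 0 in the control.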

How the results depend on the processing

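The plant-only alternatives, the same plant total, the counting intervals and the length-matched random lists were chosen after seeing the data; the others were planned. No paired analysis was possible because each dose had 1 library, and for the same reason no library was left out. Unless stated, the cause was not tested. With no filter, or with only genes that have an open reading frame, no count moved, since every gene has one and the size rule already removes weak genes.

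Counts moved with the pseudocount, the size rule and the organisms counted. With a pseudocount of 5, genes higher and lower at 2 mM numbered 546 and 336 (2641 and 1102 in the reported counts), at 4 mM 688 and 2749 (2134 and 8424), at 8 mM 823 and 1695 (2136 and 5920), and the same way at all 3 doses 11 and 144 (177 and 356). With a 4-fold rule, which passes fewer genes by construction, they were 332 and 185, 310 and 3309, and 396 and 1090 at 2, 4 and 8 mM. With an FPKM of at least 5, lower genes numbered 663, 3615 and 3269, and 32 genes were higher the same way. A pseudocount of 0.1 gave 313 genes higher the same way, and correlations across genes of 0.061 for 2 with 8 mM and 0.71 for 4 with 8 mM. Plant genes alone gave 640 genes higher at 2 mM and 1715 and 1844 lower at 4 and 8 mM, and with the same plant total 660, 1658 and 1694; mite genes are left out by construction. The remaining 50 of 72 alternative counts of 2-fold genes stayed within 1.5 times.

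Scaling moved the balance of directions. Factors other than the same plant total were computed over all genes, so they also carry the mite difference between libraries. Upper-quartile scaling shifted the all-gene median by 0.12, −0.45 and −0.21 at 2, 4 and 8 mM, trimmed-mean scaling by −0.16 at 4 mM, and the same total by 0.11 and 0.12 at 4 and 8 mM. Under upper-quartile scaling 965 genes were higher at 4 mM, 9.05% of those called against 20.2%; among plant genes the share fell from 54.9% to 25.1% at 4 mM and from 52.1% to 37.5% at 8 mM, and trimmed-mean scaling gave 44.1% at 4 mM. Lists with most members higher numbered 25, 1 and 3 at 2, 4 and 8 mM under upper-quartile scaling (16, 15 and 13 as reported), 8 at 4 mM under trimmed-mean scaling, and 24 and 21 at 4 and 8 mM with the same plant total.

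Correlations with 2 mM turned when mite genes were left out. For plant genes they were 0.26 for 2 with 4 mM (−0.20 over all genes), 0.19 for 2 with 8 mM (−0.05) and −0.15 for 2 against 0 mM with 8 against 4 mM (0.28), and with the same plant total 0.26, 0.18 and −0.15. Contrasts sharing no library do not measure the agreement of 2 mM with 4 or 8 mM. Over all genes, mite genes included, 2 against 0 mM with 8 against 4 mM gave 0.28 and 8 against 0 mM with 4 against 2 mM gave 0.67, against −0.15 and 0.73 for plant genes.

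Some list medians, with the share of members higher, changed sign. Over all members under upper-quartile scaling at 4 mM, HSP70 went from 0.29 (71.4%) to −0.14 (35.7%), abscisic acid and PP2C from 0.33 (75%) to −0.12 (33.7%) and NBS-LRR from 0.43 (67.9%) to −0.058 (48.6%). By motif, HSP70 at 4 mM was at −1.17 (36.4%). With plant members only, actin, tubulin and EF1-alpha went from 0.16 (62.3%) to −0.048 (47.3%) at 2 mM and from −0.42 (36.8%) to 0.061 (55.2%) at 8 mM, and ribosomal proteins from −0.13 (35.9%) to 0.019 (54.5%) at 4 mM. With the same plant total, actin, tubulin and EF1-alpha were at −0.028 (47.3%) and 0.13 (58.3%) at 2 and 8 mM, ribosomal proteins at 0.065 (64.7%) and 0.0078 (51.1%) at 4 and 8 mM (−0.32 and 19.3% as reported at 8 mM), and plastid- and mitochondrion-encoded genes at 0.022 (53.5%) at 8 mM (−0.13, 33.3%). Among plant members, upper-quartile scaling took plastid- and mitochondrion-encoded genes from −0.11 (32.0%) to 0.017 (52.6%) and ribosomal proteins from −0.10 (27.2%) to 0.030 (57.9%) at 2 mM, and at 4 mM abscisic acid and PP2C from 0.33 (75.8%) to −0.12 (34.1%) and NBS-LRR to −0.058 (48.6%). At 8 mM the same total took plant plastid- and mitochondrion-encoded genes from −0.06 (40.4%) to 0.070 (60.5%) and ribosomal proteins from −0.08 (32.8%) to 0.056 (59.1%), and the same plant total took them to 0.022 (53.5%) and 0.0078 (51.1%).

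Plant list medians also turned under choices other than scaling. Members found by protein motif, which are mostly fewer and partly other genes, turned 13 of 90: HSP70 at 2 and 8 mM (0.14 and −0.75), MYB at 2 mM (0.36), pathogenesis-related at 2 mM (0.12), terpene synthase at 2 mM (−0.47), xyloglucan and expansin at 2 mM (−0.18), senescence at 4 and 8 mM (−0.12 and 0.0054), ascorbate peroxidase at 4 mM (−0.0085), and at 8 mM Kunitz inhibitor and polyphenol oxidase (0.022), small heat shock protein (0.058), WRKY (−0.020) and auxin response (0.0025). The HSP70 motif set held 7 plant genes, 3 of them on the list. The Kunitz inhibitor and polyphenol oxidase set held 9, of which 4 were on the list. An FPKM of at least 5 turned 2 of 120, pathogenesis-related at 2 mM (0.15) and cytochrome P450 at 4 mM (0.017), and took flavonoid and tannin at 4 mM to −0.022. A pseudocount of 5 turned none of 123, which was hardly possible since a pseudocount keeps the sign of each gene's difference. It shrank 28 by more than 1.5 times, among them at 4 and 8 mM jasmonate synthesis (−0.64 and −0.63), xylem and secondary wall (−0.76 and −0.98), class III peroxidase (−0.59 and −0.58), terpene synthase (−1.32 and −1.22) and xyloglucan and expansin (−0.42 and −0.49), at 4 mM pathogenesis-related (−0.26), aquaporin (−0.29), AP2/ERF (−0.16) and NBS-LRR (0.26), and at 8 mM ABC transporters (0.29). By motif 24 medians kept their sign and were over 1.5 times as large, among them MYB at 4 and 8 mM (−1.11 and −1.41), glutathione S-transferase at 2, 4 and 8 mM (−0.96, −1.30 and −1.10), flavonoid and tannin at 4 and 8 mM (−2.53 and −3.28), xylem and secondary wall (−2.59 and −3.24) and NBS-LRR (0.81 and 0.84), and 9 shrank, among them ABC transporters at 8 mM (0.26).

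Of the other values, 1205 of 1323 list medians stayed within their interval, and 646 of 3276 values of named genes moved. No named gene at least 2-fold from the control turned sign, but with scaling factors of 0.71 to 1.10 and pseudocounts, which keep a gene's sign, none could. Some smaller differences turned, such as the Rubisco small chain at 4 and 8 mM under upper-quartile scaling. Motifs with fewer than 3 members gave no value. Depth limits weak genes: 55 of the 63 calls of named plant genes at 2 mM had a counting interval that excluded no difference, 131 of 133 at 4 mM and 148 of 152 at 8 mM.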

Other observations

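The tests of the wound and jasmonate genes were chosen only after the result was seen, as were the Gene Ontology terms and mite families described here; the tests of length, expression level and hour of harvest were set before their results.

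Gene Ontology terms added groups outside the fixed lists, described by plant genes. Flavonoid biosynthetic process, 26 genes, had medians of −1.56 and −2.00 at 4 and 8 mM, with 18 and 20 genes at least 2-fold lower and 0 higher. Oxylipin genes, which include jasmonate synthesis, had −1.12 and −1.04, and aromatic amino acid biosynthesis, which supplies phenylalanine to the phenolic pathways, had −0.90 and −0.79 over 33 genes. Chitinase activity, 18 genes, had +0.17 at 2 mM and −2.01 and −1.49 at 4 and 8 mM, and pectinesterase activity, enzymes that modify wall pectin, had +0.45, −0.76 and −1.18 over 24 genes. Rhythmic process had +0.86 and +0.75 at 4 and 8 mM with 11 of 26 genes at least 2-fold higher at each dose. Covalent chromatin modification had +0.47 and +0.48 over 154 genes, close to the +0.50 and +0.47 of the longest of 10 length groups of plant genes; random lists for terms were not matched on length. The term response to wounding, 36 genes, went against the wound and jasmonate lists, at +0.53 and +0.39. None of these medians changed sign under another scaling, although the scalings used could have turned few if any of them. Response to water deprivation, at +0.43 and +0.39, and mRNA processing, at +0.41 and +0.29, changed sign at 4 mM under upper-quartile scaling. Of 276 terms, 45 lay above and 62 below the central 95% of random lists at both 4 and 8 mM, and 20 lay above at 2 mM and below at both higher doses.

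The mite transcripts also differed in composition. Vitellogenins, the yolk proteins of egg-laying females, made up 1.10%, 3.81%, 0.738% and 1.03% of mite FPKM at 0, 2, 4 and 8 mM. Cuticle proteins made up 4.25%, 2.97%, 3.51% and 2.62%, and mite cytochrome P450s 0.577%, 0.604%, 0.632% and 0.931%.

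The pooled median of the wound and jasmonate lists was lower at 4 and 8 mM, although most members did not pass 2-fold and the term response to wounding went the other way: 146 plant members of 4 lists (144 at 8 mM) had medians of −0.13 at 2 mM (12 higher and 17 lower, a sign lost under upper-quartile scaling), −0.69 at 4 mM (5 and 64) and −0.62 at 8 mM (4 and 58), against plant medians of −0.17, +0.22 and +0.13. Between 8 and 4 mM their median was +0.0879 with an interval over genes of −0.042 to 0.19, just above the plant median of −0.051. This met the bound written against a fall graded with dose, but only narrowly. Genes are not replicates of a dose and each dose is 1 library, so the values do not decide the question. By list, Kunitz inhibitors with polyphenol oxidases were at +0.83 (interval 0.09 to 1.23) and JAZ repressors at +0.48 (−0.08 to 1.48) in this contrast. Jasmonate synthesis was at +0.11 (−0.06 to 0.42), and the pathogenesis-related list, the largest, at −0.05. The mite load may account for the pattern, since mite FPKM was also lower at 4 mM and less so at 8 mM. At 2 mM, however, with the most mite RNA, the interval of the pooled members, −0.21 to −0.03, included the plant median. The 4 lists lay on both sides of that plant median of −0.17. The pathogenesis-related list, the largest, was above it at −0.004. Jasmonate synthesis was at −0.20, JAZ repressors at −0.30 and Kunitz inhibitors with polyphenol oxidases at −0.60. Dose and mite load cannot be told apart with 1 library per dose. Another difference between the 0 and 2 mM libraries and the 4 and 8 mM libraries also stays open: 4 against 0 mM and 8 against 2 mM, which share no library, correlated at 0.648 across plant genes, and the labels give no batch. The 8 mM library also stood apart in pig-matched genes, with a summed FPKM of 3.45 against 1566, 1198 and 1525 at 0, 2 and 4 mM. An effect of pHBA, the difference the design names, stays among the open explanations.

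The plant ABC transporters and NBS-LRR receptors had list medians of +0.45 and +0.43 at 4 mM and +0.49 and +0.37 at 8 mM, although upper-quartile scaling took the 4 mM values to 0.00 and −0.06 and protein motifs took ABC transporters to +0.26 at 8 mM. Upper-quartile scaling took the 4 mM median of all plant genes from +0.22 to −0.25, so both lists stayed above it. Only 29 of 120 ABC and 22 of 109 NBS-LRR members were at least 2-fold higher at 4 mM, with 7 and 8 lower, and 29 of 118 and 19 of 110 at 8 mM, with 9 and 8 lower. Long transcripts were weighed as the cause, but among random lists matched on coding length the lower percentile over both doses was 99.44 for ABC transporters and 98.43 for NBS-LRR genes. Weak expression was weighed too, and for members with a mean FPKM of at least 5 the percentiles were 98.97 and 99.51. Assembled coding length and weak expression are thus argued against as the whole cause. The match used coding sequences as assembled de novo, in 5 length groups, so it cannot speak to the length of the full transcripts. An effect of pHBA may be a candidate explanation, and the mite load, which differs between the same libraries, was not tested for these lists.

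The 13 clock genes, set from general knowledge, had a median of +1.23 at both 4 and 8 mM, with 8 of 8 evening genes at least 2-fold higher at 4 mM and 7 of 8 at 8 mM, but 4 and 6 under upper-quartile scaling, which also turned 2 of the 5 morning genes at 4 mM. The 8 evening genes are assembled genes that carry only the names APRR5, GIGANTEA and APRR1. Some share an assembly cluster, such as TRINITY_DN17945_c0_g1 and TRINITY_DN17945_c0_g3, so they may not be 8 separate loci. GIGANTEA (TRINITY_DN18190_c1_g1), an evening gene, was at 30.2, 27.3, 86.9 and 90.7 FPKM at 0, 2, 4 and 8 mM, and LHY (TRINITY_DN17899_c0_g1), a morning gene that turned, at 1446, 1365, 2023 and 2075. A trend with assembled coding length is argued against by a percentile of 100 among length-matched lists, whose members were drawn as separate genes. A different hour of harvest could move evening genes against morning genes, and the evening median minus the morning median was 0.898 at 8 mM and 0.959 at 4 mM, between the bounds of 0.5 and 1 set beforehand. The hour of harvest and the dose cannot be told apart, since the labels give no hour and each dose has 1 library.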
